A study of Homo sapiens and Mus musculus with 20 samples.

How the data were processed

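The data were lists of enriched regions from 20 libraries, 1 per group, grouped by the titles and genotype and antibody labels. The labels' protocols describe formaldehyde fixation, sonication, immunoprecipitation on magnetic beads and tagmentation of the bead-bound DNA.

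Per the submitters' processing notes, Trimmomatic, FastQC, MultiQC, Bowtie2 and MACS2 2.1.2 were used with GRCh38. Per the file headers, the peak caller was MACS 2.2.7.1 for the ARP1 input, H3K27ac and H3K27me3 libraries and 2.1.1.20160309 for the others. GRCh38 is also the build in the notes for the mouse libraries, whose contigs are those of the mouse; their build is not given in the sources used here. Per the file headers, regions were called per library with no control and no local background, at a q-value of 0.05, so the background was the mean of the same library and gains of DNA copy number or repeats can give regions. The HA and KDM6A libraries were called from single-end tags with a fragment length of 200 bp, and the others from fragments. Duplicates were removed during calling for ARP1 input, H3K27ac and H3K27me3, where the headers give redundant rates of 0.36 to 0.61. They were also removed for the HA and KDM6A libraries, at rates of 0.04 to 0.05. The rate was 0.00 for H3K4me1 and MEF. Each deposited row gives a pileup signal, a fold enrichment (ratio), a −log10 p-value and a −log10 q-value, all the authors' own values for that region. They were used only to rank or filter regions within a list.

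Rows that shared coordinates were summits of 1 region and were merged, and contigs other than the numbered chromosomes and X were left out. Regions were counted as shared with at least 1 bp of overlap. The gene table was RefSeq GRCh38.p14 with 19974 protein-coding genes. It gives no strand, so the transcription start planned for could not be placed, and a gene was called marked when a region lay within 2.5 kb of either gene end. A gene was lost when marked in WT and unmarked in the mutant, and gained in the opposite case. Without a mouse annotation, MEF regions were counted in place of genes, as planned.

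Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Overlaps were set against 100 circular shifts of the second list along each chromosome. Gene lists were fixed before the data were examined, and each count is given as a percentile of 10000 random lists matched on decile of WT rank, ties being split evenly. For HA and KDM6A regions the class was the decile of WT H3K27ac rank, with unmarked genes in a class of their own, and for KARPAS there was no matching. Gains were set against unmatched lists of unmarked genes. Losses common to both mutants used 1000 draws within deciles. Covered base pairs used genes with at least 500 bp in WT.

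Named genes were the 10 with the highest ranked gene-end region (−log10 q, then fold) in 1 list and no region within 10 kb of a gene end in the other, in each direction. For KDM6A and HA they were the 10 highest ranked in the WT-only or tagged-only set. KDM6A, CIITA, NLRC5, members of the MHC lists whose state differed and up to 4 members of each other list were added. These rules, the designs and the first set of alternatives were fixed before the data were examined. That set was −log10 q of at least 5, equal list lengths, windows of 1 kb and 10 kb or 50% overlap, and removal of regions on ARP1 input. Window alternatives were not run for MEF. Alternatives added after seeing the data removed KDM6A regions on the WT HA list, 289 bins of 1 Mb with over 10 times the median count of regions, chromosomes 2 and 11, or H3K27me3 regions on H3K27ac.

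Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The overlap, gene-end and list functions were tested on simulated data, and 5 of 5 steps returned the seeded answer.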

Results

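Lists of enriched regions were available for 20 chromatin immunoprecipitation libraries, 16 human and 4 mouse. ARP1, a human multiple myeloma cell line, was profiled with KDM6A labelled wild type (WT), knocked out (KO) or JmjD-dead, a label that names the demethylase domain of KDM6A. H3K27ac, H3K27me3 and input DNA were profiled in all 3 ARP1 genotypes, and H3K4me1 in WT and KO. KDM6A itself was precipitated from ARP1 WT and KO cells and from KARPAS, a line also labelled multiple myeloma. An HA antibody was used on a line labelled WT and on a line titled as HA-tagged whose genotype label reads knock out. Mouse embryonic fibroblasts (MEF), WT and Kdm6a KO, gave H3K27ac and H3K27me3. Each group had 1 library, so no difference below has a replicate check, and the 95% intervals (exact Clopper-Pearson for shares) cover counting error only. After the authors' filtering, in units of 1000000 (M), the H3K27ac libraries of ARP1 held 25.6 (KO), 30.8 (WT) and 31.2 (JmjD-dead) M fragments, and the H3K27me3 libraries 6.60, 5.03 and 10.4 M. The inputs held 0.725, 0.384 and 0.223 M fragments in the same order. The H3K4me1 libraries held 34.0 (WT) and 25.6 (KO) M fragments, and the MEF libraries 13.6 to 36.6 M. The HA libraries held 16.6 (WT) and 25.3 (tagged) M tags, and the KDM6A libraries 11.9 (ARP1 WT), 20.2 (ARP1 KO) and 37.4 (KARPAS) M.

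The KDM6A gene was examined first, since it is the gene the genotypes name. The windows at its ends held an H3K27ac region in all 3 ARP1 genotypes, on chromosome X at 44871677 to 44872931 in WT and 44871214 to 44872865 in KO (GRCh38). An H3K4me1 region was listed there in WT, at 44871936 to 44872958, and none in KO, where 51.8% of the genes marked with H3K4me1 in WT held no region. Region lists do not show whether the coding sequence was disrupted, so they do not check the genotype labels.

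Regions of a KDM6A antibody and of an HA antibody were each set against a background list in ARP1. The labels do not say whether the HA-tagged protein was added back to KO cells, so HA regions are given as such and not as KDM6A sites. The HA regions found in the tagged line without a region in the WT HA list lay at many genes of plasma cell identity. Of 20 plasma cell genes 12 held such a region, among them IRF4, a transcription factor needed by plasma cells, SDC1 (the surface marker CD138), CD38 and TNFRSF17, which encodes BCMA. That count lay at percentile 99.3 of 10000 random lists matched on WT H3K27ac rank, as a description of these libraries. In all, 14 gene lists were compared in this way for each set of regions, and the percentiles are not adjusted for their number. Random lists draw genes without regard to position, so percentiles take no account of neighbouring members that share a region. TAP2, PSMB8, TAP1 and PSMB9, all with such a region, adjoin on chromosome 6. Of 21 MHC class I and antigen processing genes 11 held such a region (percentile 97.7), including B2M, the invariant chain of class I molecules, the peptide transporter genes TAP1 and TAP2, and NLRC5, the class I transactivator. Of 30 interferon-stimulated genes 7 did (percentile 98.2), among them OAS1, OAS2 and ISG15, and of 26 immune ligand and adhesion genes 8 did (percentile 97.3), among them CD58 and MICB. T and NK markers, genes of other cell types, held 4 of 14, namely CD2, TRAT1, CD3E and CD3G (percentile 98.8), against 0 in the WT HA list. HOX genes held 1 of 39 (percentile 1.61) and housekeeping genes 6 of 20 (percentile 45.6). The WT HA list, the background here, itself marked 13 of the 21 class I genes (percentile 94.8), 13 of the 20 plasma cell genes (percentile 89.2) and 13 of the 20 housekeeping genes (percentile 96.9). Without 1 Mb bins dense in regions, an alternative chosen after seeing the data, the tagged-only counts were 8 of the 20 plasma cell genes, 9 of the 21 class I genes, 6 of the 30 interferon-stimulated genes, 6 of the 26 immune ligand and adhesion genes and 2 of the 14 T and NK markers. With −log10 q of at least 5, the counts were 10, 5, 5, 5 and 3 in the same order.

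**Figure D1:**
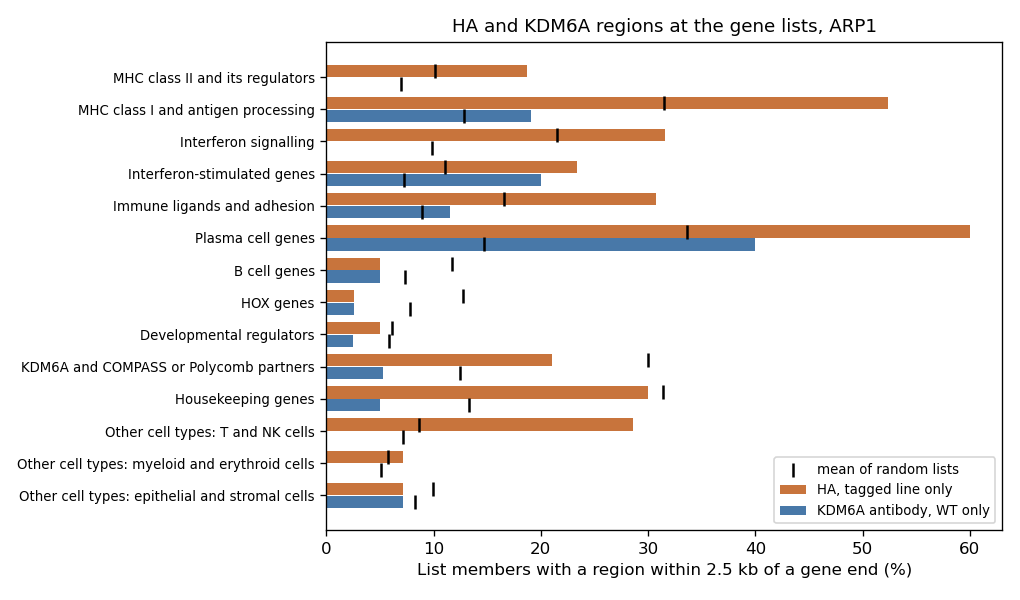
Share of each gene list's members (horizontal axis, percent) with a region within 2.5 kb of a gene end, for HA regions found in the tagged line only and KDM6A antibody regions found in WT only; black ticks give the mean of 10000 random lists. Plasma cell genes stand highest for both antibodies, with 12 and 8 of 20 members.

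Plasma cell genes also stood out with the KDM6A antibody. Regions of the WT library without a region in the KO library marked 8 of the 20 plasma cell genes (percentile 99.8), among them SLAMF7, XBP1 and IRF4. They also marked 6 of the 30 interferon-stimulated genes (percentile 98.9), including IFIT1 and BST2, and 4 of the 21 class I genes (percentile 80.2), which were TAP2, PSMB8, TAPBP and NLRC5. None of the 16 MHC class II genes was marked, CIITA included. The KO library, the background here, itself marked 6 of the 20 plasma cell genes, 1 of the 21 class I genes and 0 of the 30 interferon-stimulated genes, out of 846 genes in all. At NLRC5 both antibodies listed a region within 2.5 kb of the gene's start coordinate, on chromosome 16 at 56990297 to 56990627 for KDM6A and 56990345 to 56990687 for HA. The highest ranked gene-end regions of the WT-only set lay at GALNT5, the amylase genes AMY1A, AMY1B and AMY1C, WHAMM, CHST12, NEGR1, HILPDA, FOXN1 and MAL2. The amylase genes are near-identical copies, so their regions are uncertain. In the HA tagged-only set the highest ranked regions included those at EMB, GOLM2, MAP1LC3B2, LOC124901373, BTLA and HHLA2, both genes of immune checkpoint molecules, C1GALT1, POLR3GL and SOWAHD.

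Of 90964 KDM6A regions in ARP1 WT, 63118 (69.4%) had no KO region, and of 54338 HA regions in the tagged line 28120 (51.8%) had none in the WT HA list. Between these sets 10335 KDM6A WT-only regions overlapped an HA tagged-only region, 16.4% (16.1 to 16.7), against a mean of 484 in 100 random placements. More of the KDM6A WT-only regions, 27924 or 44.2% (43.9 to 44.6), overlapped the WT HA list, against a mean of 1110 in random placements. That list is longer, with 78725 regions, and the ratios to random placement were 25.2 for it and 21.3 for the tagged-only set. It is also longer than the full list of the tagged line, from 16.6 M tags against 25.3 M. H3K27ac regions of WT cells covered 62.8% (62.2 to 63.4) of the HA tagged-only regions and 22.4% (22.0 to 22.7) of the KDM6A WT-only regions, where random placement gave 3.32% and 3.17%. The library labelled KO that serves as the KDM6A background had 2846 of its 44936 regions (6.33%) in the block of chromosome 2 from 15 to 20 Mb, where the WT library had 62 of 90964. Keeping KDM6A regions outside the WT HA list left 35194 WT-only regions, leaving out 289 dense bins across the genome left 28229, and leaving out chromosomes 2 and 11 left 54864.

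In KARPAS the KDM6A regions lay at genes of the B lineage. Of 20 B cell genes 14 held a region (percentile 100 of random lists not matched on rank), where the ARP1 WT KDM6A list held 1. The lists differ in reach, as the KARPAS list marked 4975 genes from 37.4 M tags and the ARP1 WT list 1937 from 11.9 M. Plasma cell genes held 13 of 20, immune ligand and adhesion genes 16 of 26, MHC class I genes 12 of 21 (percentile 99.9) and MHC class II genes 6 of 16 (percentile 86.5). A region lay at CIITA, the class II transactivator, on chromosome 16 at 10868155 to 10869210. Housekeeping genes held 8 of 20 (percentile 92.9) and T and NK markers 7 of 14 (percentile 97.7). Developmental regulators held 3 of 40 (percentile 0.305). Of the 55867 KARPAS regions 8204 (14.7%, 14.4 to 15.0) overlapped an ARP1 KDM6A WT-only region, against a mean of 913 in random placements. No KARPAS background list was analysed here, and the difference between the lines was not tested.

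In KO cells nearly every gene marked with H3K27ac, a mark of active promoters and enhancers, still held a region near an end. A weaker region counted as retained. Of 12313 genes marked in WT, 238 (1.93%, 1.70 to 2.19) held no region in KO, and 654 of the 7661 unmarked genes (8.54%, 7.92 to 9.18) held one. Counted by region, 20820 of 69127 WT regions (30.1%) had no KO region, and 26852 of 76242 KO regions (35.2%) had no WT region. The highest ranked losses were TMEM98, H2BN1, JCAD, LILRA2, OLFML3, ARHGAP15, GPR82, TMEM156, SYT6 and SPRR4. The region at TMEM98 lay on chromosome 17 at 32940381 to 32942588 and ranked 14427 of 69127 in the WT list. Gains were led by KATNAL1, MT1F, a metallothionein, C6orf58, PTPRH, BCL11A, a transcription factor of B cell development, MX2, an interferon-induced antiviral gene, PTPN14, GPR132, LOC107987025 and CD9. The region at KATNAL1 lay on chromosome 13 at 30306646 to 30307908 and ranked 12562 of 76242 in the KO list.

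**Figure D2:**
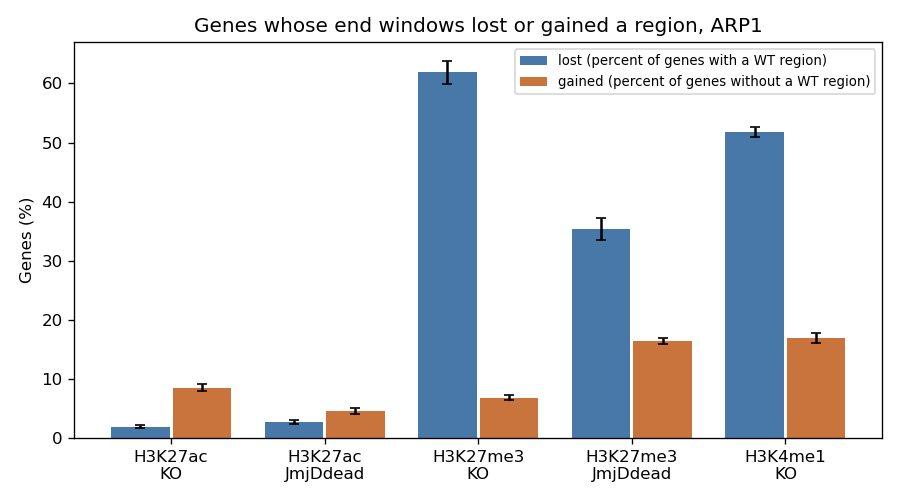
Genes (vertical axis, percent) whose end windows lost a region among genes marked in WT, or gained one among genes unmarked in WT, for each mark and ARP1 mutant; error bars are exact 95% binomial intervals of counting error. H3K27ac losses stand at 1.93% and 2.75%, against 61.9% and 35.4% for H3K27me3.

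Nearly all antigen presentation genes marked in WT kept an H3K27ac region of some strength. All 21 class I genes were marked in WT, KO and JmjD-dead cells, and 5, 4 and 5 of the 16 class II genes were. HLA-DMA, which helps load peptides on class II molecules, was the 1 member of the 37 that lost its region in KO, a count at percentile 89.4 of matched random lists. The count was 0 with −log10 q of at least 5 and with windows of 10 kb, and H3K27ac covered 175 bp at HLA-DMA in WT and 152 bp in KO. No region was listed at HLA-DRA in any of the 3 genotypes. Marked genes could still hold a weaker region. The best H3K27ac region at NLRC5 ranked 12705 of 69127 in WT, 28047 of 76242 in KO and 19712 of 74063 in JmjD-dead cells. At CIITA the ranks were 8061, 6769 and 15556. Both genes also counted as marked with H3K4me1 in KO. Their regions ranked 45975 (NLRC5) and 45683 (CIITA) of 80845 there, against 6413 and 8399 of 95729 in WT. Base pairs covered by H3K27ac regions within each gene and 10 kb either side gave a finer measure, chosen after seeing the data. The median KO over WT ratio was 0.990 for the 21 class I genes and 1.10 for 13964 genes (percentile 8.21 of matched lists). At NLRC5 the covered length was 19058 bp in WT, 14562 bp in KO and 17165 bp in JmjD-dead cells. CIITA had 9740, 10513 and 5669 bp, B2M 9291, 7405 and 9010 bp, and TAPBP 11457, 15951 and 11677 bp. Interferon-stimulated genes had the lowest list median in KO, 0.894 over 14 genes (percentile 0.45), with 6 genes above 1 and 8 below. HOX genes had 1.25 over 25 genes (percentile 97.0). These lengths move with how much was called in each library.

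All 20 housekeeping genes and all 19 genes of the list of KDM6A with COMPASS and Polycomb genes kept a region in both mutants. So did the 19 plasma cell genes marked in WT. Among interferon-stimulated genes OAS3 lost its region in both mutants. Of the 18 unmarked in WT, MX2 and IFIH1 gained one in KO (percentile 66.95 of random lists). IFIT1, USP18, IFIH1 and GBP1 did in JmjD-dead cells (percentile 99.5). PDCD1LG2, which encodes the checkpoint ligand PD-L2, gained a region in both mutants, and CD274 (PD-L1) in JmjD-dead cells. For the immune ligand and adhesion list this was 1 of 11 unmarked genes in KO (percentile 56.75) and 2 of 11 in JmjD-dead cells (percentile 95.1). The same list lost 2 of 15 marked genes in JmjD-dead cells, LGALS9 and ULBP3 (percentile 90.6). Markers of other cell types were marked in 5 of 14 (T and NK), 2 of 14 (myeloid and erythroid) and 5 of 14 (epithelial and stromal) genes in WT, with 6, 2 and 6 in KO and 6, 3 and 4 in JmjD-dead cells. Of the 5 epithelial and stromal markers 3 lost their region in JmjD-dead cells, CDH5, COL1A1 and KDR (percentile 97.4), and COL1A1 also did in KO. KRT8 and KRT18, keratins of simple epithelia, gained regions in both mutants, 2 of 9 unmarked list members (percentile 96.6 in JmjD-dead cells and 89.2 in KO). Whether both genes were marked by the same region was not examined.

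In JmjD-dead cells 338 genes lost H3K27ac (2.75%, 2.46 to 3.05) and 351 gained it (4.58%, 4.12 to 5.07). The highest ranked losses were TREML2, PELI2, COL4A4, ARHGAP15, HRH2, PRKCB, HERC5, TRIM5, PMCH and ITPRIPL2. The gains were led by CYP19A1 (aromatase), NRG2, ZNF532, HDGFL1, KLRC1, KATNAL1, C6orf58, ZNF432, TBC1D3K and GLUD2. TBC1D3K has near-identical copies. Of 21 HOX genes marked in WT, 5 lost their region, among them HOXA6, HOXA7, HOXB2 and HOXC11 (percentile 99.6), while none did in KO. By covered base pairs the HOX list showed no such shift, with a median JmjD-dead over WT ratio of 0.981 over 25 genes (percentile 40.5). The median for all genes was 0.982. Which of losses and gains was larger turned with equal list lengths (364 and 319). Both mutants lost 117 genes in common, where losses drawn independently within deciles of WT rank gave a mean of 50.3 and a maximum of 69 in 1000 draws, and independent lists gave 6.53. Gains were shared by 200 genes, against 29.96 for independent lists. Both mutants were compared with the same WT library, so part of the excess may come from that library.

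Of the WT H3K27ac regions that overlapped a KDM6A WT-only region, 3075 of 13825 (22.2%) had no KO region, and of the others 17745 of 55302 (32.1%). Averaged over deciles of WT rank the difference was 1.37 percentage points (0.555 to 2.19) in the other direction, higher at KDM6A sites. This interval is a normal approximation that treats regions as independent. It was −0.477 when 50% overlap was required and −1.42 without dense bins, and 4.6 with −log10 q of at least 5 and 2.32 with equal list lengths. It was 1.25 without regions on input and 0.463 without KDM6A regions on the WT HA list.

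H3K27me3, the repressive mark that KDM6A removes, was listed at 2570 genes in WT, 2169 in KO and 4512 in JmjD-dead cells. KO cells lost 1590 of the WT genes (61.9%, 59.96 to 63.8) and gained 1189. JmjD-dead cells lost 910 (35.4%, 33.6 to 37.3) and gained 2852. The highest ranked losses in KO were GTF3C5 with LOC124902325 (1 region), C1orf159, BOD1, TREML2, GLT6D1, ACY3, RPS15, FAM76A and IL6R, the interleukin 6 receptor. Gains in KO were led by TTLL8 with MLC1 (1 region), TMEM141, CCNF, OXCT1, PRRC2A, PRRT4, COX8A, LRRC37A3 and MAT2A. In JmjD-dead cells FAM83G, DGKD, MOSPD3, RNF113A with NDUFA1, GDNF, PDE4D, ARPC1B, ZC3HAV1 and LYZL2 led the losses, and TTLL8 with MLC1, LOC124904605, PRKAB2 with CHD1L, SEPTIN8, TBRG4, FAM90A20, FAM90A16 and TNNT3 the gains. The FAM90A genes are near-identical copies, so their regions are uncertain. Among the 2 MHC lists regions lost in KO included those at HLA-B, RFXANK, HLA-DMB and ERAP1, and regions were gained at HLA-E, PSMB10, RFX5, PSME2 and PDIA3. Class I genes gained 4 of 12 in KO (percentile 99.6) and 7 of 12 in JmjD-dead cells, and housekeeping genes 4 of 12 and 6 of 12 (percentile 99.6 for both). These random lists were not matched on H3K27ac, which all 21 class I and 20 housekeeping genes held in WT. In KO 1189 of all 17404 genes unmarked in WT gained H3K27me3, and 1085 of the 9877 that held H3K27ac in WT. The percentiles may therefore reflect the presence of H3K27ac. Of the genes marked in WT, KO lost 3 of 9 class I genes (percentile 8.48) and 7 of 8 housekeeping genes (percentile 90.4).

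These H3K27me3 regions lay on H3K27ac regions of the same line, in 98.1% (97.0 to 98.9) of the top 1000 in WT, 97.4% in KO and 99.3% in JmjD-dead cells. Over all regions the shares were 64.4% (63.7 to 65.1), 70.8% (70.0 to 71.6) and 50.6% (50.1 to 51.1). HOX genes were marked in 3 of 39 and developmental regulators, usual Polycomb targets, in 2 of 40 in WT, against 8 of 20 housekeeping genes. Which of losses and gains was larger turned in KO with stricter regions (190 lost, 635 gained) and with equal list lengths (980 lost, 1380 gained), and in JmjD-dead cells with equal lengths (1142 lost, 702 gained). Genes that lost H3K27ac and gained H3K27me3 in KO numbered 6, against 22.4 for independent lists among 9877 genes. They were REG4, FAM47E-STBD1, DUX4, LOC124905413, FAM90A8 and ZNF541. The named set was chosen after its values were seen, and DUX4 and FAM90A8 have near-identical copies. The comparison with 22.4 cannot decide whether genes switched from H3K27ac to H3K27me3. As 70.8% of KO H3K27me3 regions lay on KO H3K27ac regions, a low count can follow from that overlap alone. The value of 22.4 was also not matched on WT rank.

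H3K4me1, a mark of enhancers, was compared by region between WT and KO. Of 95729 WT regions 72115 (75.3%) had no KO region, and of 80845 KO regions 55954 (69.2%) had no WT region. The KO list was weaker, with 16063 regions at −log10 q of at least 5, against 42217 in WT. Losses by region or by gene therefore cannot be told apart from lower enrichment in the KO library. The highest ranked WT regions with no KO counterpart lay at TRIB1, NFYA, FRMD8, NRDC, FMC1 with LUC7L2 and FMC1-LUC7L2, CD164, DDIT4, a stress response gene, and BRD2, a reader of acetylated histones. Gains were led by CORIN, LOC124905977, LOC105378947, HOATZ, VSNL1, HSPB2, FCRL4, URAD, LOC124905938 and RUNDC3B. Of 19 plasma cell genes marked in WT 7 lost their regions, among them PRDM1 and XBP1, regulators of plasma cell differentiation (percentile 39.6). Of the 5 T and NK markers unmarked in WT 4 gained a region, namely CD3G, KLRD1, CD8B and CD3D (percentile 99.8), while 5 of the 9 marked ones lost theirs (percentile 39.8). Of the 11 B cell genes unmarked in WT 4 did, CD79B, CD37, FCER2 and CXCR5 (percentile 93.9), while 6 of the 9 marked ones lost theirs (percentile 81.3). WT H3K27ac regions covered 59.8% of the WT H3K4me1 regions and 25.5% of the KO ones.

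The library labelled KO for H3K4me1 also stood apart in where its regions lay. It had 3348 of its 80845 regions (4.14%, 4.01 to 4.28) on chromosome 2 from 15 to 20 Mb, where WT had 107 (0.112%) and the KO H3K27ac library 122 (0.160%). From 9 to 14 Mb it had 645 (0.798%), where WT had 2468 (2.58%) and KO H3K27ac 1542 (2.02%). In a block of chromosome 11 that includes the HOATZ region (111536570 to 111542338) and HSPB2 it had 1716 (2.12%), where WT had 88 (0.0919%), and the KO KDM6A library had 3.22% of its regions there. Of the leading gains VSNL1 and LOC124905977 lie in the 15 to 20 Mb block of chromosome 2. Leaving out 289 dense bins across the genome took the gains to 21595, and leaving out chromosomes 2 and 11 took them to 41302.

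**Figure D3:**
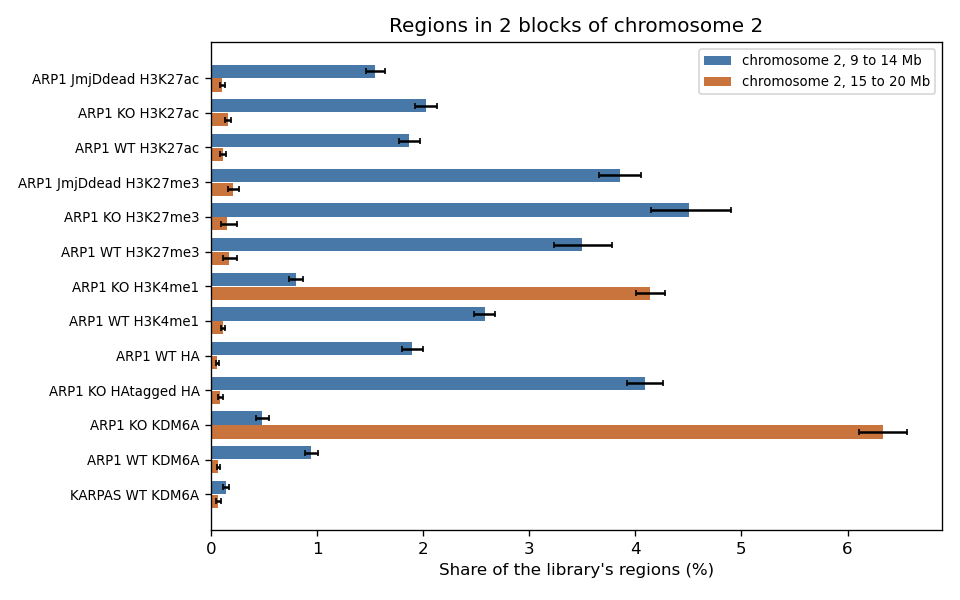
Share of each library's regions (horizontal axis, percent) in 2 blocks of chromosome 2, with exact 95% binomial intervals of counting error. The KO H3K4me1 and KO KDM6A libraries hold 4.14% and 6.33% of their regions from 15 to 20 Mb.

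In MEF the H3K27ac lists were of like size and the H3K27me3 list was shorter in KO. For H3K27ac 75579 of 170119 WT regions (44.4%) had no KO region and 93125 of 194389 KO regions (47.9%) had no WT region. Losses outnumbered gains with −log10 q of at least 5 (17085 and 12744) and with equal list lengths (79517 and 74552). For H3K27me3 134587 of 191871 WT regions (70.1%) had no KO region, and 34706 of 100887 KO regions (34.4%) had no WT region. The KO library had 13.6 M fragments and the WT library 24.0 M. Chromosome X held 20683 H3K27me3 regions in WT, 10.8% (10.6 to 10.9) of the list, and 5247 in KO, 5.20% (5.07 to 5.34). The H3K27ac regions on X were 2.36% in WT and 1.72% in KO. H3K27me3 regions overlapped H3K27ac in 3.44% (WT) and 3.75% (KO), below the 7.95% and 8.46% of random placements. Among the top 1000 H3K27me3 regions the shares were 42.5% (39.4 to 45.6) and 31.7% (28.8 to 34.7). Genes were not named because no mouse annotation was used here.

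**Figure D4:**
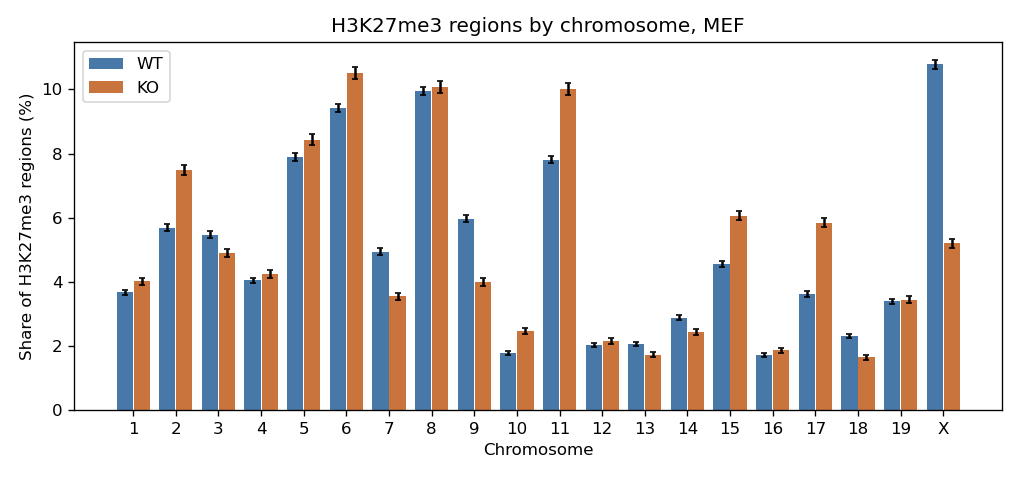
Share of H3K27me3 regions (vertical axis, percent) on each chromosome in MEF WT and KO, with exact 95% binomial intervals of counting error. Chromosome X falls from 10.8% in WT to 5.20% in KO.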

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

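The tests on regional density in the KO libraries that used the chromosome 2 block, and both tests on H3K27me3, were chosen after the results were seen; the rank correlation test and the MEF tests were not.

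For H3K27me3, gained minus lost genes came to −401 in KO and 1942 in JmjD-dead cells. Neither direction was stable: equal list lengths turned both (980 lost and 1380 gained in KO, 1142 and 702 in JmjD-dead cells), and with −log10 q of at least 5 both mutants had more gains than losses (190 lost and 635 gained, 170 and 552). The difference between the mutants was not tested, and with 1 library each it has no replicate check. Input libraries were in no comparison of the genotypes, and their regions lay on H3K27ac regions of the same line in 22.0% (WT), 19.4% (KO) and 23.1% (JmjD-dead) of cases, above the highest of 100 random placements (3.88%, 4.04% and 4.33%).

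The top 1000 ARP1 H3K27me3 regions of each library lay mostly on H3K27ac regions. An effect of depth cannot be told apart: the deepest library, JmjD-dead, had 99.3% of its top 1000 regions there but 50.6% of all regions, below WT (64.4%) and KO (70.8%), and depth differs along with the genotype. A background of open chromatin is a candidate explanation: of the WT input regions with −log10 q of at least 5, 84.7% (80.9 to 88.0, 354 of 418) lay on WT H3K27ac regions. True presence of both marks on different alleles or cells stays open and was not tested.

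The KO H3K4me1 and KO KDM6A libraries shared dense blocks of regions. A gain carried by 1 KO line used for every KO library is argued against by the KO H3K27ac library, where the share of the block from 15 to 20 Mb was 1.47 times that of WT, against a bound of 5, and settings of the caller by the WT H3K4me1 library, called the same way, with 0.112% of its regions there. Whether these 2 libraries came from cells with another copy number profile cannot be told apart from the alternatives: their Spearman rho over 2928 bins of 1 Mb outside the blocks was 0.538, below the 0.678 of KO H3K4me1 with KO H3K27me3, so the test fixed in advance went against it. That bound takes no account of the antibody. In a check added after that result, the WT libraries of the same 2 antibodies had a rho of 0.458, against up to 0.949 with another library. For KO KDM6A, 0.538 was its highest rho, above the 0.507 with WT KDM6A. On chromosome X, KO H3K4me1 had 0.387% of its regions and KO KDM6A 0.692%, against 2.11% and 3.64% in WT. KO H3K27ac had 2.31% there, but the H3K27me3 libraries were low in both KO (0.303%) and WT (0.461%). The KO H3K4me1 and KO KDM6A libraries also had low shares from 9 to 14 Mb (0.798% and 0.481%, against 2.02% in KO H3K27ac). WT KDM6A was low there as well (0.942%). So were the inputs of KO (0.786%), WT (0.750%) and JmjD-dead cells (0.582%). The WT input was low although WT H3K27ac had 1.87%, so the KO input does not bear on this question.

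Chromosome X held a smaller share of H3K27me3 regions in MEF KO. The test of fewer fragments in KO went against that explanation, as the WT over KO ratio of that share was 1.88 among the top 50000 regions of each list. It cannot decide, since it equalised list lengths and not depth. Autosomes also shifted, with ratios of 1.94 on chromosome 13 and 0.542 on chromosome 17. Fewer copies of X in the KO cells may contribute, since the KO over WT ratio of the X share was 0.746 for the top H3K27ac regions, below the lowest autosome (0.812). The fall is not particular to X in the top H3K27me3 regions, where chromosome 13 had a lower KO over WT ratio (0.516) than X (0.532). An effect of Kdm6a loss on X stays open, as untested.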

How the results depend on the processing

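The stricter regions, equal list lengths, windows, 50% overlap and input removal were chosen before the data were examined, and the other settings after. Of 114 recomputed values 63 stayed within 1.5 times the main count or its interval, 35 moved further and 16 changed the larger of losses and gains or the sign. The H3K27ac losses and gains in ARP1 KO and the losses common to both mutants stayed within 1.5 times under every setting run. Windows of 1 kb and 10 kb were not run for MEF, where regions were counted. The cause was not tested for the changes below, except that stricter, equal or filtered lists hold fewer regions.

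With −log10 q of at least 5, KDM6A WT-only regions numbered 36757, HA tagged-only 17926, their overlap 6751 and the KARPAS overlap 4995. H3K27ac losses in JmjD-dead cells came to 219. H3K27me3 counts were 190 lost and 635 gained in KO, which turned the order, and 170 and 552 in JmjD-dead cells. H3K4me1 had 37605 lost and 11458 gained. MEF had 17085 lost and 12744 gained for H3K27ac, which turned the order, and 18204 and 3079 for H3K27me3. Antigen presentation losses were 0, and the KDM6A site difference was 4.6 percentage points.

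With equal list lengths KDM6A WT-only regions numbered 25975, their HA overlap 6701 and the KARPAS overlap 4341. The order turned for H3K27ac in JmjD-dead cells (364 lost, 319 gained) and in MEF (79517 and 74552), and for H3K27me3 in KO (980 and 1380) and JmjD-dead cells (1142 and 702). H3K27me3 losses in MEF were 56587, and the KDM6A site difference was 2.32.

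With 1 kb windows the order turned for H3K27ac in JmjD-dead cells (288 lost, 283 gained). H3K27me3 counts were 810 and 742 in KO and 537 and 1706 in JmjD-dead cells, and 3 genes lost H3K27ac while gaining H3K27me3. With 10 kb windows H3K27me3 losses in KO were 2616, antigen presentation losses 0 and genes with both changes 12; without input regions the last was also 12. With 50% overlap the KDM6A site difference was −0.477.

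Without KDM6A regions on the WT HA list, WT-only regions numbered 35194, the KARPAS overlap 4724 and the site difference was 0.463. Without dense bins these were 28229, 4406 and −1.42, and H3K4me1 gains 21595. Without H3K27me3 regions on H3K27ac, H3K27me3 losses and gains in KO were 913 and 463. Depth differed between libraries and no setting equalised it, so differences in list length are not separated from depth.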

Other observations

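KRT8 and KRT18 in ARP1 also gained H3K27me3 and H3K4me1 regions in KO. These gains are not independent support for the H3K27ac gains. Of all KO H3K27me3 regions 70.8% lay on KO H3K27ac regions, and the KO H3K4me1 library stood apart in where its regions lay. Epithelial and stromal markers as a list had a median KO over WT ratio of covered H3K27ac length of 1.48 over 6 genes (percentile 97.5), with 6 of 6 above 1. In JmjD-dead cells the same list had 1.06.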
